A study of Mus musculus with 48 samples.

How the data were processed

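RNA levels were measured on 48 Affymetrix MOE430v2 expression arrays, which read mouse transcripts with oligonucleotide probe sets. The cells were C2C12, an established line of mouse myoblasts that fuse into myotubes when serum is lowered. The labels place the arrays in 16 groups of 3: growth medium 24 h before induction and at 0 h, differentiation medium at 12 times from 0.5 h to 144 h, and cycloheximide, an inhibitor of protein synthesis, at 1 h and 3 h of differentiation. Per the labels' protocols, growth medium held 20% fetal bovine serum, differentiation medium held 2% horse serum, the drug was added 1 h before induction at 50 µM, and total RNA taken with Trizol was labelled as biotinylated cRNA from 5 µg.

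The deposited values are on a log2 scale and come from RMA, per the submitters' processing notes; RMA is a method that corrects background, normalizes probe intensities between arrays and summarises them per probe set. The sources used here do not give the version of RMA, or say whether all arrays were processed in one run. The values were used as deposited. The table held 45101 probe sets, of which 64 were controls. Array medians ran from 4.00 to 4.16 and array means from 5.02 to 5.05 on the 42 arrays without cycloheximide. On the 6 cycloheximide arrays the medians ran from 4.20 to 4.24 and the means from 5.24 to 5.26, so the 2 sets of arrays were not on one distribution. For that reason each count of genes changed by cycloheximide is given as deposited and after quantile normalization of the 48 arrays again. The correlation between arrays of a group ran from 0.9818 to 0.9955, and no arrays were identical. With 3 arrays per group, their number limits the precision.

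A gene symbol was listed for 35890 probe sets, several symbols or identifiers for 932 and no gene for 9160. Probe sets with exactly 1 symbol were used, 34945 in all, which covered 18193 genes. Each gene was represented by its probe set with the highest mean over the 48 arrays, which mattered for the 9010 genes with more than 1 probe set. The chosen probe set had a name ending in _x_at or _s_at, which marks possible cross-hybridisation, for 1545 genes. No genome was used, so no positions are given. Members of the gene lists without a matching single-symbol probe set were not analysed here. Probe sets listed under the symbol of a small RNA were tested and counted, but none of their values is given.

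Differences between groups were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 48 arrays, which leaves 32 residual degrees of freedom, with moderated statistics from eBayes at its default settings. All tests were two-sided. Adjusted p values are Benjamini-Hochberg values over the 18193 genes within a comparison, and a gene was called changed at an adjusted p under 0.05. Differences are log2 fold changes with their standard errors (SE) from the model, and levels are means with the standard deviation (SD) of 3 arrays. Every time was compared with 0 h, 0 h with 24 h before, each cycloheximide group with the untreated cells of its time and with 0 h, and the change in cycloheximide effect between 3 h and 1 h was tested as an interaction. An F-test covered all 12 differentiation times against 0 h. The labels name no drug-treated cells at 0 h.

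Lists of genes were fixed for immediate early genes, myogenic transcription factors, sarcomere, excitation-contraction coupling and synapse, muscle energy metabolism, adhesion and fusion, DNA replication, mitosis, cell cycle exit, Id, Notch and other repressors of myogenesis, the insulin-like growth factor axis, extracellular matrix, cholesterol synthesis and uptake, FoxO targets and growth factor withdrawal, the unfolded protein and amino acid response, NF-kB targets and cytokines, ribosome biogenesis, the interferon response, heat shock, the circadian clock, hypoxia and glycolysis, and markers of adipocytes, bone and cartilage, smooth muscle and leukocytes. A further list of housekeeping genes served for scaling. The 25 lists were tested against all other genes with limma's camera, with the correlation between genes estimated from the data, in 8 comparisons, and p values were adjusted over the 200 tests. Members were also counted with p values adjusted over the list alone.

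Named genes were chosen by rule: at 1 h, 24 h, 144 h and for cycloheximide, the up to 10 risen and 10 fallen genes of largest change among called genes whose 3 arrays in one group all lay above the 3 of the other; elsewhere the up to 5 in each direction, with fewer printed where values repeat; up to 4 called members of each list; and always Myod1, Myog, Myf5, Mef2c, Acta1, Myh3, Ckm, Cdkn1a, Ccnd1, Id1, Id3, Fos, Egr1, Myc and Igf2. Genes with only a clone, LOC, Gm or Rik name were counted and not named. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from those said to be chosen later.

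The alternatives were trend and robust moderation, the replicate number as a block, array weights, quantile normalization again, cyclic loess, centring on the housekeeping list, the mean of a gene's probe sets, every probe set by itself, probe sets ending in _s_at or _x_at left out, genes below the 40th percentile of mean level left out, adjustment over all comparisons together, only the groups compared, 0 h and 24 h before as a joint reference, and each array left out in turn. Lists were also tested with a preset correlation of 0.01 and with fry. Added after the data were seen were a fit of the 42 arrays without cycloheximide and the second normalization for the overlap at 1 h and for the lists.

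The design text says that harvests came from growths of successive passages, but the labels do not say that a replicate number stands for a passage. Whether equal numbers vary together was checked by correlating their deviations from the group means, and in 13 of 17 comparisons every pair exceeded 0.1. The exceptions were 1 h, 144 h and cycloheximide at 1 h, and 0 h against 24 h before. Of 48 arrays, 44 correlated best with arrays of their own number. In the 13 comparisons the value with the replicate number as a block is therefore given wherever it changed a call or moved a count by over 1.5 times.

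The procedure was tested on simulated data built from the real arrays' levels and spreads. In the simulated comparison of 1 h with 0 h, 46.3% of genes changed by 0.5 log2 units were recovered, 94.0% of those changed by 1 and 100% of those changed by 2, and 4.76% of calls were false. For the simulated interaction the shares were 22.4%, 74.6% and 97.0%, with 7.86% of calls false. In a simulation with 1 moved list, camera called that list and 0 of the unmoved ones. The noise was drawn independently for each gene and array. These simulations therefore do not show how the tests do where genes or arrays vary together. Figures were drawn with matplotlib 3.10.9.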

Results

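Gene expression was followed in C2C12 cells, mouse myoblasts that leave the cell cycle and fuse into myotubes when serum is lowered. Cells in growth medium were sampled 24 h before induction and at 0 h, and cells in differentiation medium at 0.5, 1, 1.5, 2, 3, 6, 9, 12, 24, 48, 96 and 144 h. Further cells received cycloheximide, which blocks protein synthesis, 1 h before induction and were sampled at 1 h and 3 h, after 2 h and 4 h of the drug. Each of the 16 groups had 3 arrays, and 18193 genes were measured. All differences are log2 fold changes with standard errors from limma, and n = 3 arrays in every group. Genes named for the size of their change had all 3 arrays of one group above all 3 of the other. That condition was not applied to the difference between the cycloheximide effects at 3 h and 1 h.

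The comparisons of each differentiation time with 0 h ask which genes differ after the change of medium, and when. The labels name no cells in growth medium after 0 h, so the change of medium and time in culture cannot be separated. Over the day in growth medium before induction, 2388 genes changed. Immediate early genes, which respond to stimuli from pre-existing proteins, moved first in the calls against 0 h. Falls of the Id genes, which encode inhibitors of the myogenic factors, followed (Id3 called from 1.5 h, Id1 from 3 h and Id2 from 6 h). Genes of the sarcomere list were called risen from 9 h, and some already at 6 h when adjusted over the list alone. Falls of mitosis genes came at 24 h, and of most DNA replication and mitosis genes at 96 h. Many sarcomere genes had already risen, and most replication and mitosis genes fallen, over the day before induction. The number of genes called was 7 at 0.5 h, 35 at 1 h, 77 at 1.5 h, 94 at 2 h, 71 at 3 h, 92 at 6 h, 247 at 9 h, 513 at 12 h, 2544 at 24 h, 4854 at 48 h, 5924 at 96 h and 5168 at 144 h. The first time at which a gene was called was 24 h for 1994 genes and 48 h for 2704. Over all 12 times, 6951 genes changed by the F-test, 38.2% of those tested, and 2205 of these changed at least 2-fold at some time. Most calls from 1 h to 9 h rested on the spread shared by all 48 arrays. With only the 6 arrays compared, 10 genes were called at 0.5 h, 6 of them among the 7, but 12 at 1 h, 2 at 1.5 h, 4 at 2 h, 4 at 3 h, 3 at 6 h and, by limma, 0 at 9 h, where 1781 had an unadjusted p under 0.05. Those fits did not use the replicate number. With it as a block over all 48 arrays, more genes were called: 227 at 1.5 h, 328 at 2 h, 336 at 3 h, 465 at 6 h and 749 at 9 h.

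**Figure D1:**
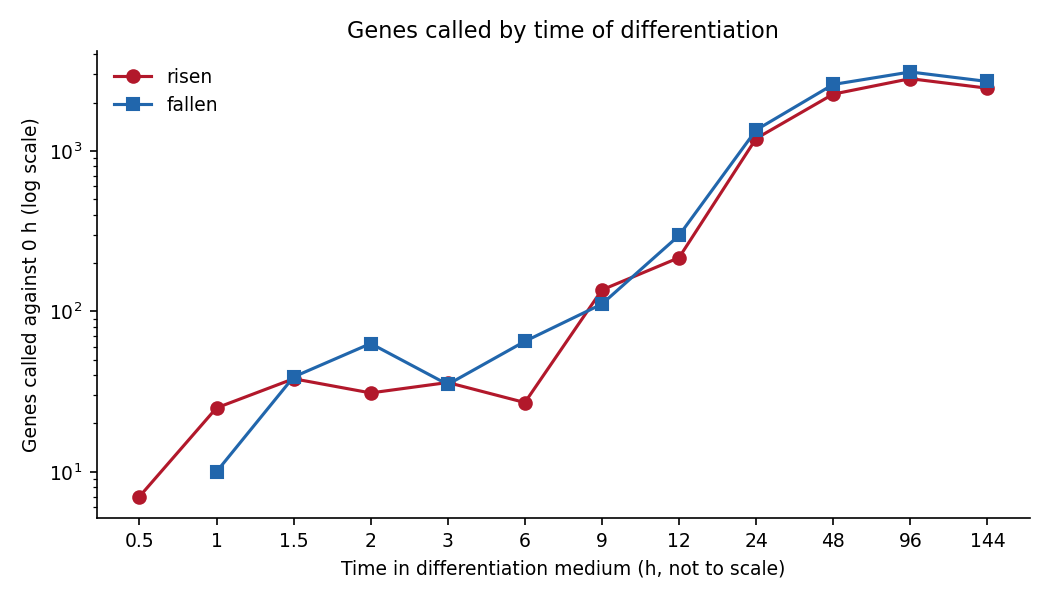
Number of genes called risen and fallen against 0 h (adjusted p under 0.05, limma) at each time of differentiation. The counts run from 7 at 0.5 h to 5924 at 96 h.

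Muscle genes were already higher at 0 h than 24 h before, while both groups of cells were in growth medium. Myog, a transcription factor of terminal muscle differentiation, rose from 5.64 ± 0.74 to 10.15 ± 1.12 (SD, n = 3), a log2 difference of 4.51 (SE 0.64). Actc1, the cardiac actin that young muscle also makes, rose by 4.36 (SE 0.69), Tnnc2, the fast troponin C, by 4.17 (SE 0.66), and the myosin light chains Mylpf and Myl1 by 3.86 (SE 0.58) and 3.71 (SE 0.58). Genes of cell division fell: Ccne2, a cyclin of entry into S phase, by 2.25 (SE 0.28), the mitotic kinesin Kif20b by 2.52 (SE 0.45) and Depdc1a by 2.25 (SE 0.37). Hmgn5, a nucleosome-binding protein, fell by 2.36 (SE 0.32) and Car8 by 2.31 (SE 0.26). This comparison asks what time in growth medium does before any change of medium.

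Of 31 sarcomere genes, 15 rose and 0 fell over that day (20 risen adjusted over the list alone), Tnnt1 by 3.37 (SE 0.37) and Acta1 by 3.11 (SE 0.60) among them. Of 13 genes of adhesion and fusion 4 rose (7 over the list alone), including Mymx, a small protein that drives fusion, by 2.75 (SE 0.49). Of 18 genes of excitation-contraction coupling 5 rose (10 over the list alone), with Chrng, an embryonic acetylcholine receptor subunit, up by 1.71 (SE 0.39). Of 25 DNA replication genes 20 fell and 0 rose (24 fallen over the list alone), Cdc6 with −1.42 (SE 0.32), and of 24 mitosis genes 16 fell and 0 rose (24 fallen over the list alone), Bub1 by 1.46 (SE 0.32). Camera passed none of these lists over this day, with adjusted p = 0.289, 0.166, 0.31, 0.0556 and 0.21. Myogenic transcription factors gave 5 risen of 11 (5 over the list alone, camera adjusted p = 0.21), Myod1 by 0.91 (SE 0.28, adjusted p = 0.0214), a call lost without 0 h replicates 1 or 2 or the replicates 1 or 3 of 24 h before (adjusted p 0.0621 to 0.167).

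The lists that passed camera here were FoxO targets, the insulin-like growth factor axis and extracellular matrix upward, and heat shock downward. Of 17 FoxO targets, genes that rise when growth factor signals weaken, 9 rose and 0 fell (10 and 1 over the list alone, adjusted p = 0.0194), Txnip by 1.89 (SE 0.20) and the ubiquitin ligase Fbxo32 by 1.15 (SE 0.25). In the insulin-like growth factor axis 5 of 9 rose (7 over the list alone, adjusted p = 0.0487), Igfbp5 by 1.37 (SE 0.22), and Igf2 had 2.60 (SE 0.92, adjusted p = 0.0568), which passed without 0 h replicate 3 (0.0485). Of 22 matrix genes 13 rose and 2 fell (14 and 3 over the list alone, adjusted p = 0.0487), decorin (Dcn) by 2.88 (SE 0.38) and the collagen gene Col6a2 by 2.08 (SE 0.22). Of 11 heat shock genes 5 fell and 0 rose (5 over the list alone, adjusted p = 0.0153), Hsph1 by 1.05 (SE 0.18). Centring on housekeeping genes ended 3 of these calls: heat shock (0.239; camera alternatives 0.00142 to 0.239), FoxO targets (0.354; 4.79e-06 to 0.354) and matrix (0.324; 1.33e-07 to 0.324, with 0.0638 after cyclic loess and 0.0794 on the mean of probe sets).

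Further lists held called genes over the same day, and camera passed none of them. Ribosome biogenesis had 12 of 20 genes fallen and 0 risen (16 fallen over the list alone, camera adjusted p = 0.0525), among them Nop56 by 0.94 (SE 0.15) and fibrillarin (Fbl) by 0.82 (SE 0.11). Cholesterol synthesis had 4 of 15 fallen (7 over the list alone, adjusted p = 0.359), Idi1 by 1.45 (SE 0.27). Of 18 repressors of myogenesis 5 rose and 0 fell (5 over the list alone, adjusted p = 0.435), Heyl by 2.21 (SE 0.32) and Notch3 by 1.41 (SE 0.21). Of 6 adipocyte markers 2 rose (2 risen and 1 fallen over the list alone, adjusted p = 0.733), Lpl, lipoprotein lipase, by 3.22 (SE 0.61) and Cebpa by 1.37 (SE 0.26). Of 21 NF-kB targets 4 rose (4 over the list alone, adjusted p = 0.21), Vcam1 by 1.17 (SE 0.18). Of 10 genes of cell cycle exit 1 rose (4 over the list alone, adjusted p = 0.378), Gadd45a by 2.01 (SE 0.26), and of the immediate early genes 7 rose and 1 fell (11 and 2 over the list alone, adjusted p = 0.289), Egr1 by 0.78 (SE 0.15). Among the genes always named, Myh3 (2.29, SE 0.80, adjusted p = 0.0514, but 0.0244 without 0 h replicate 2) and Fos (0.77, SE 0.29, adjusted p = 0.0754) did not pass. Ccnd1, cyclin D1, fell by 0.55 (SE 0.19, adjusted p = 0.0458), a call lost without any single 0 h array or replicate 1 of 24 h before (0.0659 to 0.378). Adjusted p values of Myf5 (0.37), Mef2c (0.27), Ckm (0.89), Cdkn1a (0.59), Id1 (−0.22), Id3 (0.04) and Myc (−0.04) ran from 0.363 to 0.975. Centred on housekeeping genes, Myh3 (0.0102), Igf2 (0.0113), Fos (0.00382) and Cdkn1a (0.0345) passed. In all 2388 genes changed, 1321 risen and 1067 fallen, of which 279 and 179 at least 2-fold. Without replicate 1 of 24 h before the count was 1415, and centring on housekeeping genes, which shifted the median gene by 0.29, turned the share risen from 55.3% to 91.6%.

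Within 1 h of induction, genes of the immediate early response rose, many of them transcription factors or secreted factors. At 0.5 h Fos, part of the AP-1 transcription factor, rose from 6.85 ± 0.14 to 9.70 ± 0.37 (SD, n = 3), by 2.85 (SE 0.29, adjusted p = 1.27e-07). The matricellular protein Ccn1 rose by 1.64 (SE 0.27), Zfp36, which speeds mRNA decay, by 1.37 (SE 0.22), Ier2 by 1.37 (SE 0.25) and Nr4a1, an orphan nuclear receptor, by 1.76 (SE 0.34). At 1 h Nr4a1 was up by 3.29 (SE 0.34), Ccn2 by 2.17 (SE 0.24), Ccn1 by 2.00 (SE 0.27), Fos by 1.80 (SE 0.29) and Edn1, the endothelin peptide, by 1.52 (SE 0.13, adjusted p = 2.24e-09). The transcription factors Egr2 and Egr1 rose by 1.41 (SE 0.22) and 1.15 (SE 0.15), Errfi1, an inhibitor of the epidermal growth factor receptor, by 1.37 (SE 0.22), Ankrd1 by 1.22 (SE 0.18) and Noct, a circadian deadenylase, by 1.16 (SE 0.17). Ddit4, an inhibitor of mTORC1, fell by 1.50 (SE 0.20, adjusted p = 1.74e-05) and Socs3, a brake on cytokine signals, by 1.31 (SE 0.24, adjusted p = 0.00228).

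At 0.5 h 7 genes rose and 0 fell by limma, where 318 rises and 174 falls had an unadjusted p under 0.05. Every gene called then belonged to the 25 immediate early genes (11 risen over the list alone). The count was 4 without 0.5 h replicate 1 and 3 without 0.5 h replicate 2. The call of Nr4a1 ended without any of the 6 arrays except 0.5 h replicate 3 (adjusted p 0.055 to 0.371), that of Ier2 without 0 h replicates 2 or 3 or 0.5 h replicates 1 or 2 (0.055 to 0.195), and that of Zfp36 without 0.5 h replicate 2 (0.058). Ccn1 did not pass without the _s_at and _x_at probe sets (0.0603). At 1 h 25 genes rose and 10 fell, 15 and 4 at least 2-fold, and 19 were called without 0 h replicate 2. Of the immediate early genes 11 rose and 0 fell at 1 h (17 risen over the list alone, camera adjusted p = 1.54e-06). Myc rose by 0.99 (SE 0.22, adjusted p = 0.0378), a call lost without any of the 6 arrays except 1 h replicate 2 (0.098 to 0.309). In the list of FoxO targets 1 gene rose at 1 h (1 risen and 1 fallen over the list alone, camera adjusted p = 0.721), the transcriptional regulator Cited2 by 0.63 (SE 0.11), not called on the mean of probe sets (0.332) or centred on housekeeping genes (0.0577). The 18 genes of the unfolded protein and amino acid response had Ddit4 alone called (1 over the list alone, adjusted p = 0.377), and the NF-kB targets Socs3 and, upward by 0.88 (SE 0.16), Tnfaip3 (2 risen and 1 fallen over the list alone, adjusted p = 0.868).

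A further 7 falls at 1 h were each lost without any 1 of at least 3 arrays. Hoxa9, a homeobox factor, fell by 1.07 (SE 0.24), a call lost without 0 h replicates 2 or 3 or 1 h replicates 1 or 3 (adjusted p 0.131 to 0.551). Zfp217 fell by 0.78 (SE 0.17, lost without any array but 1 h replicate 1, 0.0677 to 0.459) and Zfp324 by 0.64 (SE 0.14, lost without any array but 0 h replicate 3, 0.0827 to 0.313). Khnyn fell by 0.69 (SE 0.14, lost without 0 h replicates 1 or 2 or 1 h replicate 1, 0.0564 to 0.098) and Phf13 by 0.64 (SE 0.12, lost without 0 h replicates 1 or 2 or 1 h replicates 2 or 3, 0.0521 to 0.0904). Tob2, an antiproliferative gene, fell by 0.59 (SE 0.13, lost without 0 h replicates 2 or 3 or 1 h replicates 1 or 2, 0.202 to 0.427) and Casp2, a caspase, by 0.53 (SE 0.12, lost without each of the 6 arrays, 0.0636 to 0.376). Tnfaip3 lost its call without 0 h replicate 2 (0.0521) or 1 h replicate 2 (0.0795). Centring on housekeeping genes, which shifted the median gene by 0.13, left 26 risen and 2 fallen genes, a share risen of 92.9% in place of 71.4%. Of the named falls it left that of Ddit4 called, with adjusted p 0.129 for Socs3 and 0.352 to 0.852 for the others. None of Myod1 (−0.10), Myog (−0.25), Myf5 (−0.51), Mef2c (−0.14), Acta1 (0.07), Myh3 (−0.08), Ckm (0.22), Cdkn1a (0.06), Ccnd1 (−0.36), Id1 (−0.90), Id3 (−0.60) or Igf2 (−0.13) passed at 1 h, with adjusted p from 0.69 to 1, although Id1 and Ccnd1 did against 0 h and 24 h before together (0.0335 and 0.0161). That joint reference also takes in the change over the day before induction.

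**Figure D2:**
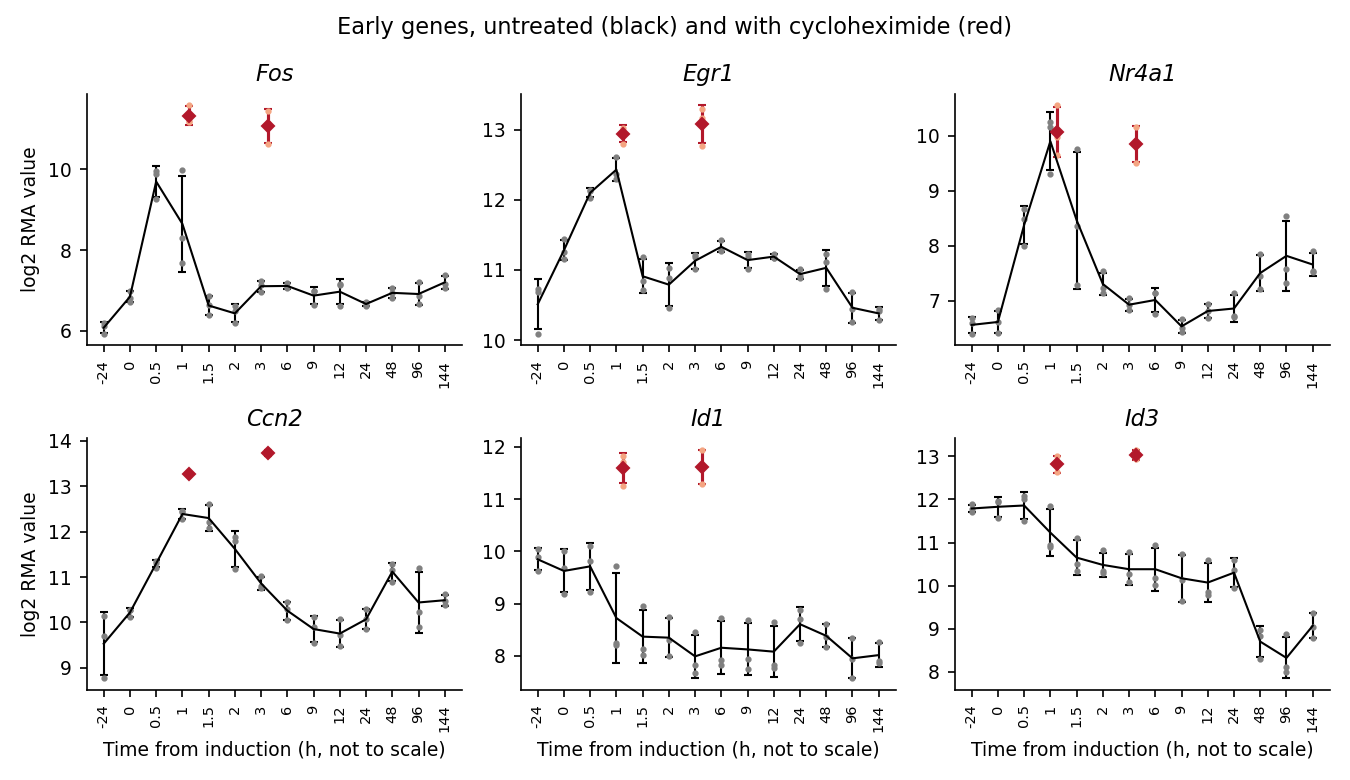
Levels (log2) of Fos, Egr1, Nr4a1, Ccn2, Id1 and Id3 over time on a stretched time axis, with points for replicates, bars for the SD (n = 3) and red diamonds for cycloheximide. Fos was highest at 0.5 h among the untreated groups, at 9.70, and reached 11.33 with cycloheximide at 1 h.

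From 1.5 h to 3 h fewer immediate early genes were called and Id genes fell. Of 25 early genes 5 were called risen at 1.5 h, 3 at 2 h and 1 at 3 h (8, 4 and 2 over the list alone), against 11 at 1 h, and 1 was called fallen at 2 h (2, 4 and 1 fallen at 1.5 h, 2 h and 3 h over the list alone). Id3 was lower than at 0 h by 1.18 (SE 0.29) at 1.5 h, 1.34 (SE 0.29) at 2 h and 1.44 (SE 0.29) at 3 h, and Id1 by 1.64 (SE 0.34) at 3 h, when it was at 7.99 ± 0.41 against 9.62 ± 0.41 (SD, n = 3). Ccn2 stayed higher by 2.09 (SE 0.24) at 1.5 h and 1.41 (SE 0.24) at 2 h, and Gadd45b, a stress response gene, by 1.33 (SE 0.22) and 1.34 (SE 0.22). Cavin4, a muscle caveolar protein, rose by 1.16 (SE 0.16) at 2 h and 1.59 (SE 0.16) at 3 h, the orphan receptor Gpr176 by 1.64 (SE 0.20) and the kinase Alpk2 by 1.48 (SE 0.21) at 3 h. The forkhead factor Foxc2 fell by 1.07 (SE 0.19) at 1.5 h and 1.05 (SE 0.19) at 2 h, and Pde4b, which breaks down cyclic AMP, by 1.02 (SE 0.15) at 2 h. Noct was up by 1.52 (SE 0.17) at 1.5 h and Lzts1 by 1.25 (SE 0.17) at 2 h.

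Of the 18 repressors of myogenesis 3 fell and 0 rose at 3 h (4 fallen over the list alone): Id1, Id3 and Smad7, a brake on TGF-beta signals, the last by 0.69 (SE 0.15). Camera did not pass that list (adjusted p = 0.293), but did with the replicate number as a block (0.0208). Ribosome biogenesis, where by limma 0 of 20 members were called at 3 h and 8 had an unadjusted p under 0.05 (5 risen over the list alone), had a camera adjusted p of 0.0942, and of 0.0243 with the block. Several of these calls ended when 1 array was left out. That leaves fewer arrays in the group, so a lost call does not by itself mark an outlying array. Id3 lost its call at 1.5 h without any array but 1.5 h replicate 1 (0.0976 to 0.308), at 2 h without 0 h replicates 1 or 2 or 2 h replicates 2 or 3 (0.0712 to 0.123) and at 3 h, like Id1, without 0 h replicates 1 or 2 or 3 h replicates 2 or 3 (0.051 to 0.105). Smad7 lost it without any array but 0 h replicate 3 (0.0576 to 0.155).

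At 1.5 h 38 genes rose and 39 fell, at 2 h 31 and 63, and at 3 h 36 and 35. With the replicate number as a block the totals were 227, 328 and 336 in place of 77, 94 and 71. At 1.5 h 33 genes were called without 0 h replicate 2, 27 without 0 h replicate 3, 49 without 1.5 h replicate 2 and 41 without 1.5 h replicate 3. At 2 h the count was 60, 32 and 34 without 0 h replicates 1, 2 and 3 and 29 without 2 h replicate 3. At 3 h it was 40, 18 and 47 without 0 h replicates 1, 2 and 3, and 33, 41 and 34 without 3 h replicates 1, 2 and 3. Centring on housekeeping genes gave a share risen of 13.7% in place of 31 of 94 genes at 2 h and 15.6% in place of 50.7% at 3 h, with median shifts of −0.14 at both times, and quantile normalization again gave 44.9% at 2 h.

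At 9 h and 12 h some muscle structural genes rose, and Id2 was low from 6 h to 12 h. At 6 h Cavin4 was up by 1.49 (SE 0.16), Tfrc, the transferrin receptor that brings in iron, by 1.66 (SE 0.29) and Gpr176 by 1.29 (SE 0.20). Apobec2 and Klhl40 were also among the largest called rises at 6 h. Id2 fell by 1.68 (SE 0.32) at 6 h, 1.94 (SE 0.32) at 9 h and 1.84 (SE 0.32) at 12 h, and Id3 by 1.66 (SE 0.29) at 9 h and 1.75 (SE 0.29) at 12 h. The growth factor Hgf fell from 7.68 ± 0.22 at 0 h to 5.87 ± 0.10 at 12 h (SD, n = 3), a change of −1.81 (SE 0.25), and had fallen by 1.51 (SE 0.25) at 9 h. Myl4, the embryonic myosin light chain, rose by 2.69 (SE 0.59) and Klhl41, a sarcomere assembly factor, by 2.71 (SE 0.57) at 9 h. Casq2, a calcium store protein, rose by 3.06 (SE 0.53) and Myh3, the embryonic myosin heavy chain, by 3.19 (SE 0.80) at 12 h, when Cd24a fell by 1.99 (SE 0.39).

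Sarcomere genes called were 0 of 31 at 6 h by limma, where 20 had an unadjusted p under 0.05, then 10 at 9 h and 19 at 12 h, all risen (14, 23 and 23 over the list alone). At 12 h the sarcomere list had a camera adjusted p of 0.067 and the 18 genes of excitation-contraction coupling, of which 4 rose (8 over the list alone), one of 0.0753. With the replicate number as a block these were 0.00513 and 0.00813. In adhesion and fusion 5 of 13 rose and 1 fell at 12 h (6 and 3 over the list alone, adjusted p = 0.352), Mymx by 2.60 (SE 0.49) and Cav3, the muscle caveolin, by 1.42 (SE 0.26). In cell cycle exit 2 of 10 rose (3 risen and 1 fallen over the list alone, adjusted p = 0.525), Cdkn1c, an inhibitor of cyclin-dependent kinases, by 2.48 (SE 0.30). Vegfa fell by 0.70 (SE 0.15) at 12 h in the list of hypoxia and glycolysis, where 1 of 12 rose and 1 fell (1 and 4 over the list alone, adjusted p = 0.21). Its call ended without 0 h replicate 2 (0.0946) or 12 h replicate 3 (0.072), and on the mean of probe sets (0.0621).

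Some of these calls also ended when 1 array was left out. At 6 h that of Id2 ended without 0 h replicate 1 (adjusted p = 0.0547), and at 9 h those of Myl4 and Klhl41 without 0 h replicate 2 or 9 h replicate 1 (0.0935 to 0.159). At 12 h that of Myh3 ended without 0 h replicates 2 or 3 or 12 h replicates 1 or 3 (0.0565 to 0.176). At 6 h 27 genes rose and 65 fell, at 9 h 136 and 111, and at 12 h 216 and 297, of which 85 and 48 at least 2-fold. Counts with the block were 465, 749 and 1149 in place of 92, 247 and 513. At 6 h 38, 28 and 56 genes were called without 0 h replicates 1, 2 and 3, and 23 and 35 without 6 h replicates 1 and 3. At 9 h the count was 76 and 116 without 0 h replicates 2 and 3 and 79 without 9 h replicate 1. At 12 h it was 195 and 292 without 0 h replicates 2 and 3 and 227 without 12 h replicate 3. Quantile normalization again gave a share risen of 39.4% in place of 29.3% at 6 h and 52.7% in place of 42.1% at 12 h.

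At 24 h of differentiation muscle genes were high, and 18 of 24 mitosis genes were lower. Myl4 rose from 6.16 ± 0.70 to 11.67 ± 0.20 (SD, n = 3), by 5.51 (SE 0.59). Mybph, a myosin-binding protein, rose by 5.41 (SE 0.77), Itgb1bp2, a muscle integrin-binding protein, by 5.35 (SE 0.50), Myh3 by 5.27 (SE 0.80), Casq2 by 5.00 (SE 0.53). Myoz2, a Z-disc protein, rose by 4.97 (SE 0.38), Ckm, muscle creatine kinase, by 4.91 (SE 0.55), Smpx by 4.86 (SE 0.67), and the troponins Tnni2 and Tnnt3 by 4.65 (SE 0.56) and 4.46 (SE 0.66). The largest falls were of the surface antigen Cd24a (−2.95, SE 0.39), Cthrc1 (−2.83, SE 0.41), Hgf (−2.59, SE 0.25) and F3, tissue factor (−2.28, SE 0.22). Next came Car3 (−2.20, SE 0.50), Ranbp3l (−2.18, SE 0.29) and the growth factor Fgf7 (−2.09, SE 0.28). Kazald1 had −2.07 (SE 0.30), Cenpf, a kinetochore protein, −2.05 (SE 0.52) and the peptidase Phex −1.98 (SE 0.43).

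Of 31 sarcomere genes 28 rose and 0 fell at 24 h (30 over the list alone, camera adjusted p = 0.0439). Of 18 genes of excitation-contraction coupling 13 rose and 0 fell (13 over the list alone, adjusted p = 0.0194), among them Cacna1s, the voltage sensor, by 2.87 (SE 0.27). Of 14 genes of muscle energy metabolism 9 rose and 0 fell (9 over the list alone, adjusted p = 0.0487), myoglobin (Mb) by 3.80 (SE 0.50). Myogenic factors gave 6 risen and 1 fallen of 11 (6 and 1 over the list alone, adjusted p = 0.31): Tead4 rose by 2.91 (SE 0.32), Myog by 2.50 (SE 0.64) and Mef2c by 2.10 (SE 0.45), while Myf5, a factor of proliferating myoblasts, fell by 1.50 (SE 0.35). Adhesion and fusion gave 7 risen and 2 fallen of 13 (8 and 4 over the list alone, adjusted p = 0.272), Cav3 by 3.81 (SE 0.26) and Mymk, a membrane protein of fusion, by 4.22 (SE 0.73). Of 24 mitosis genes 18 fell and 0 rose (24 fallen over the list alone, adjusted p = 0.21), Mki67, the proliferation marker, by 1.66 (SE 0.42), and of 25 DNA replication genes 7 fell and 0 rose (11 over the list alone, adjusted p = 0.372), Pola1 by 1.48 (SE 0.34). Cell cycle exit gave 4 risen and 1 fallen of 10 (5 and 2 over the list alone, adjusted p = 0.721), Cdkn1c by 4.15 (SE 0.30) and Cdkn1a, the kinase inhibitor p21, by 2.09 (SE 0.36).

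Camera passed no other list at 24 h. Of the repressors of myogenesis 5 rose and 5 fell (8 and 7 over the list alone, camera adjusted p = 0.942, with a direction opposite to the list's median), Heyl up by 1.58 (SE 0.32) and Id3 down by 1.53 (SE 0.29). Of the FoxO targets 2 rose and 5 fell (2 and 5 over the list alone, adjusted p = 0.417), Trim63, a muscle ubiquitin ligase, up by 2.80 (SE 0.29) and Pdk4 down by 1.62 (SE 0.19). Of 20 genes of ribosome biogenesis 7 rose (11 over the list alone, adjusted p = 0.377), Nop2 by 0.86 (SE 0.16). Of 22 matrix genes 3 rose and 3 fell (3 and 5 over the list alone, adjusted p = 0.547), with the collagen cross-linking enzyme Lox down by 1.53 (SE 0.25). Acta1, skeletal actin, rose by 3.60 (SE 0.60), Ccnd1 fell by 1.03 (SE 0.19) and Id1 by 1.02 (SE 0.34). Igf2 had 2.21 (SE 0.92, adjusted p = 0.11), which passed with the replicate number as a block (9.48e-05), whereas Myod1 had 0.05 (SE 0.28), Fos −0.18, Egr1 −0.34 and Myc −0.20, with adjusted p from 0.137 to 0.935. Without single arrays, Myog lost its call (0 h replicate 2, 0.0535), as did Cenpf (0 h replicate 3, 0.0549) and Id1 (0 h replicates 1 or 2 or 24 h replicates 2 or 3, 0.0681 to 0.152). In all 1194 genes rose and 1350 fell, 286 and 278 at least 2-fold. The total of 2544 was 1642 without 0 h replicate 3 and 1606 without 24 h replicate 1, and centring on housekeeping genes gave a share risen of 31.1% in place of 46.9%.

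**Figure D3:**
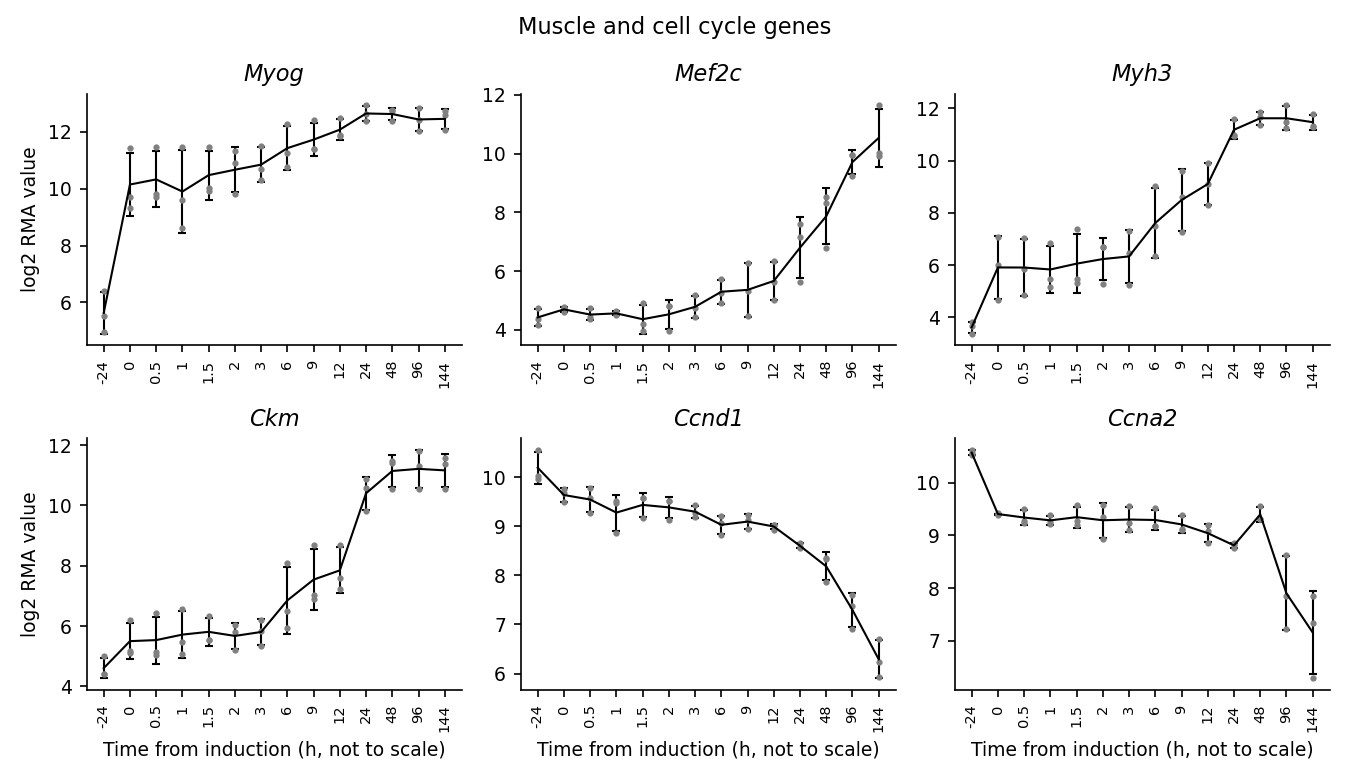
Levels (log2) of Myog, Mef2c, Myh3, Ckm, Ccnd1 and Ccna2 over time on a stretched time axis, with points for replicates and bars for the SD (n = 3), without the cycloheximide groups. Myog went from 5.64 at 24 h before induction to 10.15 at 0 h.

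At 48 h and 96 h muscle genes were high, and at 96 h cell cycle genes were low. Myoz2 was up by 6.36 (SE 0.38) at 48 h and 7.09 (SE 0.38) at 96 h, when it stood at 11.57 ± 0.11 against 4.48 ± 0.24 at 0 h (SD, n = 3), and Mb was up by 6.55 (SE 0.50) at 96 h. Lpl fell (−3.97, SE 0.61, and −4.54, SE 0.61), as did F3 (−4.04, SE 0.22, and −4.26, SE 0.22). At 48 h the secreted Wnt antagonist Sfrp2 had −3.90 (SE 0.53) and the vessel growth factor Angpt1 −3.46 (SE 0.56). Ptn, a secreted growth factor, had −3.90 (SE 0.21) and Smc2, a condensin subunit, −3.55 (SE 0.50) at 96 h. Cholesterol synthesis had 12 of 15 members risen and 0 fallen at 48 h (12 over the list alone), with Dhcr7 up by 1.39 (SE 0.27), and 8 at 96 h (8 over the list alone). Of 24 mitosis genes 6 had fallen at 48 h and 24 at 96 h (6 and 24 over the list alone), Bub1 by 2.99 (SE 0.32) at 96 h, and of 25 replication genes 3 and 23 (1 and 23 over the list alone). Sarcomere genes risen were 30 of 31 at both times (30 over the list alone). In all 2259 genes rose and 2595 fell at 48 h, and 2820 and 3104 at 96 h. Centring on housekeeping genes shifted the median gene by −0.17 at 48 h and gave a share risen of 18.9% in place of 46.5%.

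At 144 h the contractile, calcium-handling and energy genes of muscle were high and the cell cycle genes low. Smpx rose from 4.32 ± 0.71 to 11.64 ± 0.09 (SD, n = 3), by 7.33 (SE 0.67). Myoz2 rose by 7.30 (SE 0.38), Myl4 by 7.17 (SE 0.59), Mb, which stores oxygen, by 6.83 (SE 0.50), Itgb1bp2 by 6.81 (SE 0.50). Tceal7 rose by 6.80 (SE 0.30), Mybph by 6.57 (SE 0.77), Myh1, an adult fast myosin, by 6.49 (SE 0.70), Cav3 by 6.37 (SE 0.26) and Tnnt3 by 6.30 (SE 0.66). Among the falls the water channel Aqp1 had −4.78 (SE 0.21), F3 −4.55 (SE 0.22) and the neurofilament Nefl −4.52 (SE 0.55). Ptn had −3.84 (SE 0.21), Prkar2b, a regulatory subunit of protein kinase A, −3.75 (SE 0.25) and Lpl −3.74 (SE 0.61). The adhesion molecule Clmp had −3.72 (SE 0.20), Blnk −3.62 (SE 0.35), Igfbp2, which binds insulin-like growth factors, −3.56 (SE 0.24) and Crybg1 −3.53 (SE 0.19).

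The lists that passed camera at 144 h were energy metabolism, with 13 of 14 risen (14 over the list alone, adjusted p = 0.00348), excitation-contraction coupling, with 16 of 18 risen (16 over the list alone, adjusted p = 0.0152). So did sarcomere, with 30 of 31 risen (30 over the list alone, adjusted p = 0.0465), and DNA replication and mitosis, with 23 of 25 and 24 of 24 fallen (23 and 24 over the list alone, both 0.0487). No member of these lists moved the other way. Examples are Cox8b, up by 5.28 (SE 0.24), Casq1, up by 6.05 (SE 0.21), Uhrf1, which maintains DNA methylation, down by 2.78 (SE 0.24), and Nusap1, a spindle protein, down by 3.17 (SE 0.27). The replication list's call ended on the mean of probe sets (0.0513; camera alternatives 2.03e-20 to 0.0684). Of the myogenic factors 6 rose and 1 fell (7 and 2 over the list alone, adjusted p = 0.352): Mef2c rose by 5.83 (SE 0.45), Myf6 by 2.44 (SE 0.35) and Myog by 2.31 (SE 0.64), and Myf5 fell by 2.49 (SE 0.35). Acta1, Myh3 and Ckm were up by 4.09 (SE 0.60), 5.56 (SE 0.80) and 5.66 (SE 0.55), Cdkn1a by 2.60 (SE 0.36), and Ccnd1 had −3.35 (SE 0.19), Id1 −1.61 (SE 0.34), Id3 −2.76 (SE 0.29) and Egr1 −0.90 (SE 0.15). Myod1 (−0.04), Fos (0.36), Myc (−0.46) and Igf2 (1.30) did not pass (adjusted p 0.121 to 0.938). Against 0 h and 24 h before together Fos (0.0179), Myc (0.0456) and Igf2 (0.00928) did. That joint reference also takes in the change over the day before induction, so these passes are not of differentiation alone.

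Camera did not pass the further lists at 144 h. The matrix had 4 risen and 3 fallen (5 and 5 over the list alone, camera adjusted p = 0.942), periostin (Postn) up by 2.47 (SE 0.35) and Col1a1 by 1.36 (SE 0.15). Cell cycle exit had 5 risen and 2 fallen (5 and 2 over the list alone, adjusted p = 0.721), and adhesion and fusion 7 and 4 (7 and 4 over the list alone, adjusted p = 0.586). NF-kB targets had 3 risen and 8 fallen (3 and 8 over the list alone, adjusted p = 0.313), with the chemokine Cxcl5 down by 2.80 (SE 0.26). The clock list had 2 risen and 2 fallen (3 and 2 over the list alone, adjusted p = 0.929), Bhlhe40 up by 1.77 (SE 0.17). Hypoxia and glycolysis had 3 and 0 (3 and 0 over the list alone, adjusted p = 0.843, with a direction opposite to the list's median), Egln3 up by 2.52 (SE 0.14). The unfolded protein response had 2 and 1 (2 and 1 over the list alone, adjusted p = 0.875), Herpud1 up by 1.63 (SE 0.14). Interferon response genes had 0 of 11 called by limma, and 1 with an unadjusted p under 0.05 (camera adjusted p = 0.942). Camera passed no list of markers of other cell types. Adipocyte markers had 1 risen and 3 fallen of 6 (1 and 3 over the list alone, adjusted p = 0.435). Bone and cartilage had 1 fallen of 6 (1 over the list alone, adjusted p = 0.929, direction opposite to the median), Sox9 by 0.66 (SE 0.12). Smooth muscle had 1 risen of 6 (1 over the list alone, adjusted p = 0.843), Tagln by 1.19 (SE 0.29), and leukocyte markers 1 fallen of 8 (1 over the list alone, adjusted p = 0.942, direction opposite to the median), Cd14 by 0.99 (SE 0.20). In all 2459 genes rose and 2709 fell, 658 and 868 at least 2-fold. Over the 200 list tests, the sign of the median or mean differed from camera's direction in 50, of which 14 concerned cycloheximide at 1 h and 15 at 3 h. With camera's preset correlation 48 further list calls passed and 0 of the 18 were lost, by camera.

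**Figure D4:**
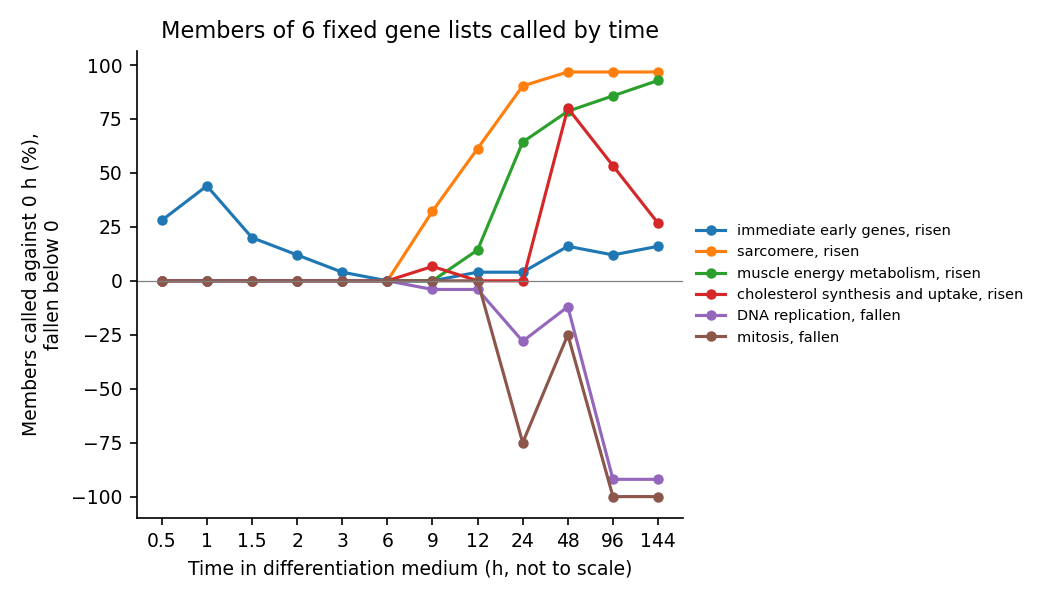
Share of measured members of 6 fixed lists called risen (above 0) and fallen (below 0) against 0 h, in percent, at each time of differentiation. Sarcomere genes called went from 10 of 31 at 9 h to 30 at 144 h.

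Cycloheximide raised immediate early genes, cytokine genes and Id genes above the untreated cells of the same time. At 1 h Dusp2, a phosphatase that ends MAP kinase signals, rose from 5.09 ± 0.35 to 8.43 ± 0.12 (SD, n = 3), by 3.34 (SE 0.18) as deposited and 3.03 after quantile normalization again. The noncoding RNA Chaserr rose by 3.02 (SE 0.30, 2.77 after normalization again), Zfp36 by 2.98 (SE 0.22, 2.75), the stress gene Gadd45g by 2.96 (SE 0.21, 2.87), Id1 by 2.87 (SE 0.34, 2.77). The NF-kB pathway kinase Map3k14 rose by 2.76 (SE 0.19, 2.44), Tsc22d3, a glucocorticoid-induced gene, by 2.71 (SE 0.21, 2.49), Fos by 2.68 (SE 0.29, 2.57), Taf1a by 2.66 (SE 0.19, 2.32) and the splicing kinase Clk1 by 2.65 (SE 0.41, 2.48). Named falls were of E2f8, a repressor of the cell cycle, by 0.72 (SE 0.14, 1.12 after normalization again) and Ptgds, prostaglandin D synthase, by 0.59 (SE 0.16, 0.91). These comparisons ask which transcripts change when new protein cannot be made.

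At 1 h with cycloheximide 14 of 21 NF-kB targets rose and 0 fell (14 over the list alone, 11 risen after normalization again, camera adjusted p = 7.62e-06), among them the chemokines Ccl7 and Ccl2 by 2.60 (SE 0.36) and 1.70 (SE 0.25) and Socs3 by 2.33 (SE 0.24). Of the 25 immediate early genes 17 rose and 0 fell (19 over the list alone, 15 after normalization again, adjusted p = 0.00756), Btg2 by 2.48 (SE 0.35) and Atf3, a stress-response factor, by 2.24 (SE 0.23). Of the 18 repressors of myogenesis 11 rose (14 over the list alone, 5 after normalization again, adjusted p = 0.116), Hes1, a Notch target, by 2.35 (SE 0.19) and Id3 by 1.59 (SE 0.29). Of the 14 clock genes 7 rose (7 over the list alone, 3 after normalization again, adjusted p = 0.21), Per1 by 2.19 (SE 0.20). Of the 18 unfolded protein and amino acid response genes 6 rose (6 over the list alone, 3 after normalization again, adjusted p = 0.586), Ddit4 by 2.44 (SE 0.20) and Atf4 by 1.24 (SE 0.12). FoxO targets gave 7 risen (9 risen and 1 fallen over the list alone, 3 and 1 after normalization again, adjusted p = 0.31), Txnip by 2.28 (SE 0.20). Sarcomere genes gave 1 risen of 31 (by limma 0 over the list alone, with 2 at an unadjusted p under 0.05, and 0 after normalization again, with 0 such; 0.895, with a direction opposite to the list's median).

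As deposited, 4470 genes were called at 1 h with the drug, 4394 risen and 76 fallen. After quantile normalization again 1258 were called, 764 risen and 494 fallen, since the deposited values of the median gene lay 0.20 higher with the drug. Centring on housekeeping genes left 495 calls and cyclic loess 1475. The call of Myod1 (0.92, SE 0.28, adjusted p = 0.0139) ended after normalization again (0.07), as did that of Egr1 (0.51, SE 0.15, adjusted p = 0.0127; then 0.0843). Without drug replicate 1 both also ended (0.0706 and 0.0532), as did Myod1 without 1 h replicate 3 (0.0796) and Egr1 without 1 h replicate 2 (0.064). Further named falls lost their call when 1 array was left out. That of Ackr4 (−0.75) ended without 1 h replicate 2 or drug replicates 1 or 2 (0.0511 to 0.298). That of Snhg3 (−0.73) ended without 1 h replicates 1 or 3 or drug replicates 1 or 2 (0.0581 to 0.156). Bivm (−0.49) lost its call without 1 h replicates 2 or 3 or drug replicate 1 (0.059 to 0.278), Rpl12 (−0.71) and Nrarp (−0.49) without drug replicate 1 (0.0618 and 0.0993) and Asic4 (−0.50) without 1 h replicate 1 (0.0511). On the mean of probe sets Ptgds (0.0581), Ackr4 (0.181) and Nrarp (0.061) did not pass. Myc rose by 1.50 (SE 0.22). Myog, Myf5, Mef2c, Acta1, Myh3, Ckm, Cdkn1a, Ccnd1 and Igf2 did not pass, with adjusted p from 0.324 to 0.908.

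At 3 h with cycloheximide the transcription factor gene Cebpd rose from 6.57 ± 0.20 to 11.74 ± 0.22 (SD, n = 3), by 5.17 (SE 0.21, 5.12 after quantile normalization again). Nfil3, a clock-linked repressor, rose by 5.09 (SE 0.24, 5.07), Ccl7 by 4.96 (SE 0.36, 4.71), Tcim by 4.77 (SE 0.25, 4.38), Ccl2 by 4.75 (SE 0.25, 4.63). Arrdc2 rose by 4.74 (SE 0.19, 4.35), the bile salt transporter family member Slc10a6 by 4.60 (SE 0.15, 4.23), Edn1 by 4.54 (SE 0.13, 4.33), Atf3 by 4.54 (SE 0.23, 4.21) and Adm, the vasodilator adrenomedullin, by 4.45 (SE 0.29, 4.11). Ccng2, a cyclin of growth arrest, fell by 3.13 (SE 0.21, 3.56), Snn by 2.34 (SE 0.16, 2.69), the snoRNA host Snhg3 by 2.18 (SE 0.24, 2.28), the hyaluronidase Cemip2 by 2.06 (SE 0.21, 2.46). The receptor Lgr4 fell by 1.97 (SE 0.19, 2.39), E2f8 by 1.95 (SE 0.14, 2.30), Rpl12, a ribosomal protein, by 1.95 (SE 0.20, 2.13), Snhg4 by 1.90 (SE 0.27, 2.24) and Sema4c by 1.90 (SE 0.15, 2.30).

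Of 21 NF-kB targets 19 rose and 0 fell (19 over the list alone, 18 after normalization again, camera adjusted p = 5.38e-08), Tnfaip3 by 3.36 (SE 0.16) and the cytokine Il6 by 3.19 (SE 0.22). Of 25 immediate early genes 24 rose (24 over the list alone, 22 after normalization again, adjusted p = 0.000208), Myc by 4.06 (SE 0.22), Fos by 3.98 (SE 0.29) and Egr1 by 1.95 (SE 0.15). Of 14 clock genes 10 rose (10 over the list alone, 4 after normalization again, adjusted p = 0.0487), Per1 by 4.39 (SE 0.20), a list call that ended with centring on housekeeping genes (0.164) and with the replicate number as a block (0.0681; camera alternatives 0.00215 to 0.164). Of 18 repressors of myogenesis 9 rose and 1 fell (9 and 1 over the list alone, 8 and 2 after normalization again, adjusted p = 0.413), Id4 by 3.84 (SE 0.18), Id1 by 3.63 (SE 0.34) and Id3 by 2.65 (SE 0.29). Of 17 FoxO targets 10 rose and 2 fell (10 and 3 over the list alone, 10 and 3 after normalization again, adjusted p = 0.221), Pdk4 up by 3.15 (SE 0.19) and Foxo1 by 1.82 (SE 0.22). Cholesterol synthesis had 2 of 15 fallen (2 over the list alone, 5 after normalization again, adjusted p = 0.478), Sqle by 1.10 (SE 0.17). Muscle groups were little moved, with 1 of 31 sarcomere genes risen (1 over the list alone, 1 after normalization again, adjusted p = 0.846, with a direction opposite to the list's median), Ldb3 by 1.23 (SE 0.28). Myod1 had 0.68 (SE 0.28, adjusted p = 0.055), which passed without 3 h replicate 1 (0.0451), without drug replicate 3 (0.0216) and with the replicate number as a block (2.06e-05). Myog (−0.12), Myf5 (0.57), Mef2c (−0.08), Acta1 (−0.04), Myh3 (0.20), Ckm (0.27), Cdkn1a (−0.20), Ccnd1 (0.01) and Igf2 (0.05) did not pass (0.215 to 0.973). In all 5628 genes rose and 622 fell as deposited, against 2180 and 2372 after quantile normalization again, 2692 and 1765 after cyclic loess and 1806 and 1065 centred on housekeeping genes, where the deposited values of the median gene lay 0.19 higher with the drug.

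**Figure D5:**
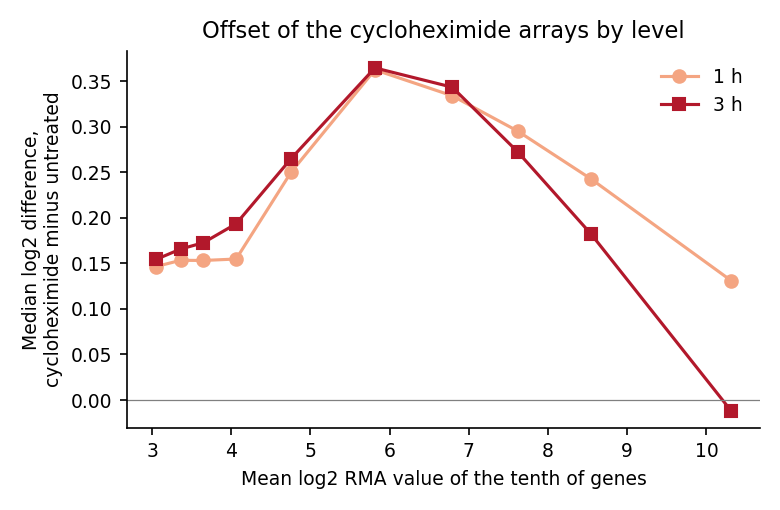
Median log2 difference between cycloheximide and untreated arrays of the same time, by 10% steps of mean gene level. The median over all genes was 0.20 at 1 h and 0.19 at 3 h, and in the brightest 10% it was 0.13 and −0.012.

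The effect of the drug differed between 3 h and 1 h for 780 genes, with 482 effects higher at 3 h and 298 lower. This test asks whether the log2 difference between treated and untreated cells moves up or down from 1 h to 3 h. An offset shared by the drug arrays cancels in it. A part that differs between 1 h and 3 h does not cancel. In the brightest 10% of genes the median difference was 0.13 at 1 h and −0.012 at 3 h. The largest gains were of Slc10a6, by 3.87 (SE 0.21), Arrdc2, an arrestin-domain protein, by 3.31 (SE 0.27), Crispld2, a glucocorticoid-induced secreted protein, by 3.15 (SE 0.26), the histone acetylation cofactor Jade2 by 3.14 (SE 0.17) and Adm by 3.10 (SE 0.41). The largest downward differences were of Sema4c, by 2.75 (SE 0.21), Ccng2 by 2.58 (SE 0.30), Lgr4 by 2.19 (SE 0.27), the repressor Klf3 by 1.96 (SE 0.25) and Snn by 1.93 (SE 0.23). A downward difference can be a deeper fall. Sema4c, Ccng2, Lgr4 and Snn were also among the largest falls with the drug at 3 h. Among immediate early genes 12 of 25 moved up and 0 down (18 up over the list alone), Myc by 2.56 (SE 0.31) and Egr1 by 1.44 (SE 0.21). Among NF-kB targets 10 of 21 moved up (13 up and 1 down over the list alone), Ccl2 by 3.06 (SE 0.36). Effects at least 2-fold apart numbered 212 upward and 91 downward. After quantile normalization again 853 genes were called, 498 upward, and centring on housekeeping genes gave 411 with a share upward of 77.1% in place of 61.8%. Array weights gave 1289 genes, and only the groups compared 457.

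All 25 genes that rose at 1 h of differentiation also rose at 1 h with cycloheximide against the same 0 h arrays. No drug-treated cells were sampled at 0 h, and the drug raised 17 of 25 immediate early genes above untreated cells at 1 h. A rise against 0 h can therefore come from the drug alone, and the overlap does not show which early rises need no new protein. Fos was up by 1.80 (SE 0.29) without the drug and 4.48 (SE 0.29) with it, Edn1 by 1.52 (SE 0.13) and 3.46 (SE 0.13), the kinase Sgk1 by 1.13 and 3.11, and Csrnp1 by 0.82 and 2.70. The others were Ankrd1, Atf3, Ccn1, Ccn2, Cited2, Dusp1, Dusp5, Egr1, Egr2, Errfi1, Maff, Myc, Noct, Nppb, Nr4a1, Phlda1, Plk2, Ptger4, Srf, Tnfaip3 and Trib1. Independent lists of these sizes would share 7.12 genes. After quantile normalization again 24 of 25 were shared against 1.11 expected, the exception being Ptger4 (0.38, adjusted p = 0.199), and at least 2-fold rises were shared by 14 of 15 against 0.256 expected. The 3 arrays at 0 h serve both comparisons and were not split, so part of the excess may come from them. Against 0 h, 5185 genes rose and 86 fell at 1 h with the drug (806 and 498 after normalization again), and 5367 and 784 at 3 h (2370 and 2719). Gadd45g was up by 3.43 (SE 0.21) and E2f8 down by 1.00 (SE 0.14) at 1 h, and Cebpd up by 5.39 (SE 0.21) and Ccng2 down by 2.82 (SE 0.21) at 3 h.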

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

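In this part the tests of separate normalization, of a rise of most transcripts, of poorer RNA, of mislabelled 0 h arrays and of a change of scale were chosen only after the result was seen. The groups of 3 arrays were not tested for single outlying arrays.

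The effect of cycloheximide differed between 3 h and 1 h for 780 genes by a test of the difference itself. Slc10a6 gained 3.87 (0.73 at 1 h and 4.60 at 3 h), Arrdc2 3.31, Crispld2 3.15, Jade2 3.14 (0.77 and 3.91) and Adm 3.10. Sema4c had −2.75 (0.85 and −1.90), Ccng2 −2.58, Lgr4 −2.19 (0.22 and −1.97), Klf3 −1.96 (0.54 and −1.42) and Snn −1.93. The dimmer probe sets gave as little as 0.14 for Jade2, −0.18 for Lgr4 and the other direction, 0.14, for Klf3.

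Of 100 random exchanges of the time labels, the real one included, 4 gave as many genes, and the highest other exchange gave 1276. The 3 other exchanges with as many all kept the times of the treated arrays, as 7 of the draws did, the real one included, and among those that mixed the treated arrays the highest count was 183. The exchanges thus point to structure, a difference of the treated arrays between 3 h and 1 h, and decide nothing about chance for the difference in effect.

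A change in the untreated cells between 1 h and 3 h is argued against as the whole cause of that difference. The median share of the difference lying in the untreated arrays was 0.134 (SE over genes 0.0135), although it exceeded 0.5 for 84 genes. That SE takes genes as independent and does not measure the spread between arrays. A longer exposure to the drug, 4 h in place of 2 h, is a candidate explanation that stays open, because time in differentiation medium and time with the drug change together. Separate normalization of the treated arrays was not put to a real test: an offset they share cancels in this difference, so that 715 of the 780 genes were called after quantile normalization again decides nothing.

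Values of most genes were higher on the cycloheximide arrays, and the gap in array mean was 7.13 times the largest range of array means within a set (0.192 against 0.027), which a separate normalization of these arrays would give. A rise of most transcripts in the cells could not be told apart from it: the dimmest 10% of genes lay 0.145 higher, within the range of 0.151 over the other 42 arrays. The Trp control, absent from mouse cells, averaged 3.22 on the treated arrays and 3.10 on the others (SD over arrays 0.054). Poorer RNA was not seen on all treated arrays: 1 of 6 lay above every untreated array of the same times in the difference between the 3-prime and 5-prime actin controls, and 3 of 6 for Gapdh. The Gapdh difference ran from −0.073 to 0.042 on the treated arrays and from −0.121 to −0.003 on those untreated arrays. Over all 42 untreated arrays it ran from −0.121 to 0.054. Somewhat poorer RNA therefore stays open.

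Muscle genes were higher at 0 h than 24 h before. Mislabelled 0 h arrays are argued against. The share of the rise lost at 0.5 h had a median of −0.0557 over the 15 risen sarcomere genes (SE over genes 0.0298, range −0.223 to 0.175). This SE takes genes as independent and leaves out the spread between arrays. Quantile normalization again moved the median gene only from 0.0126 to −0.00354, so that 15 of 15 were still called decides nothing by itself. After it the median sarcomere gene was 1.54 higher, with 16 of 31 risen and 0 fallen. The median DNA replication gene was 0.81 lower, with 20 of 25 fallen and 0 risen. For these lists the values argue against a change of scale that moves all genes alike. Time in culture and the density of the cells stay open as biological explanations and were not tested.

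Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. In each of the 17 such comparisons 1 split, the real one, gave as many genes, and the highest other split gave 0 by limma, over 153 other splits with 184 to 3783 genes at an unadjusted p under 0.05. The real counts were 7 at 0.5 h, 35 at 1 h, 77 at 1.5 h, 94 at 2 h, 71 at 3 h, 92 at 6 h, 247 at 9 h, 513 at 12 h, 2544 at 24 h, 4854 at 48 h, 5924 at 96 h, 5168 at 144 h, 2388 at 0 h against 24 h before, 4470 and 6250 with cycloheximide at 1 h and 3 h, and 5271 and 6151 with it against 0 h. For the 6951 genes that changed over the time course, 1 of 100 regroupings of the 39 arrays, the real one, gave as many and the highest other gave 2773. This argues against chance, with 1 of 100 as the lowest share possible. The regroupings mixed replicate numbers freely, although 44 of 48 arrays correlated best with their own number.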

How the results depend on the processing

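The fit of the 42 arrays without cycloheximide and quantile normalization again for the overlap and the lists were chosen only after the data were seen. So was the reading of counts without the doubted arrays, 1 h replicates 1 and 2 and 144 h replicate 1, which correlated best with another replicate number. So did replicate 2 of 24 h before, without which 2262 genes were called at 0 h, while 44 of 48 arrays correlated best with their own number. A dim gene lies near the background of the array, so its change is read as smaller than it was, and a value shows neither absence nor amount of protein. All counts below are of genes called, and where no reason is given the cause was not tested.

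With the replicate number as a block the counts were 61 at 1 h, 227 at 1.5 h, 328 at 2 h, 336 at 3 h, 465 at 6 h, 749 at 9 h, 1149 at 12 h and 1317 for the difference between cycloheximide effects. Array weights gave 14 at 0.5 h, 568 at 1.5 h, 308 at 2 h, 508 at 3 h, 540 at 6 h, 2543 at 9 h, 1984 at 12 h, 4287 at 24 h and 1289 for that difference. Quantile normalization again gave 113 at 3 h, and 1258 and 1304 with cycloheximide at 1 h against untreated cells and 0 h, where cyclic loess gave 1475 and 1452. Centring on housekeeping genes gave 25 at 1.5 h, 32 at 3 h, 41 at 6 h, 127 at 9 h, 284 at 12 h, 495 and 2871 with cycloheximide at 1 h and 3 h, 411 for the difference and 628 for cycloheximide at 1 h against 0 h. Adjusted over all contrasts together, counts were 55, 196, 430, 415, 395, 429, 624 and 900 from 0.5 h to 12 h, as the many changes of late contrasts loosen the shared threshold. With only the groups compared, which leaves fewer arrays, they were 12 at 1 h, 2 at 1.5 h, 4 at 2 h, 4 at 3 h, 3 at 6 h, 0 at 9 h (limma, with 1781 at an unadjusted p under 0.05), 2410 for cycloheximide at 1 h and 457 for the difference. With 0 h and 24 h before as the reference they were 847, 890, 1712, 995, 936, 1244, 1892, 2265 and 4434 from 0.5 h to 24 h. That reference takes in the change over the day before induction, in which 2388 genes were called. These counts are therefore not of differentiation alone.

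Every probe set by itself, which tests more features, gave 15 at 0.5 h, 122 at 3 h, 3894 at 24 h, 7898 at 48 h, 9829 at 96 h, 8413 at 144 h, 3748 at 0 h against 24 h before, 8092 and 11105 with cycloheximide at 1 h and 3 h, 9256 and 11084 for these against 0 h, and 11633 over the time course. Leaving out dim genes, which tests fewer, gave 3262 for cycloheximide at 1 h against 0 h. The overlap at 1 h was 14 for rises of at least 2-fold.

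Leaving out 1 array in turn gave 1415 to 2262 at 0 h against 24 h before, 3 to 6 at 0.5 h, 19 to 31 at 1 h, 27 to 66 at 1.5 h, 29 to 70 at 2 h, 18 to 47 at 3 h, 23 to 94 at 6 h, 76 to 255 at 9 h, 195 to 382 at 12 h and 1606 to 2226 at 24 h. The later ranges were 3562 to 4977 at 48 h, 4444 to 5919 at 96 h and 4163 to 5543 at 144 h. With cycloheximide they were 3236 to 4210 at 1 h, 5010 to 5630 at 3 h, 603 to 777 for the difference, and 3576 to 4436 and 5069 to 5538 against 0 h.

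Of 200 list tests, 18 were called. The preset correlation added 48 and lost 0, the block added 9 and lost 4, housekeeping centring added 8 and lost 4, cyclic loess added 3 and lost 1, quantile normalization again added 4 and lost 0, the mean of probe sets added 1 and lost 2, and fry added 55 in both forms and lost 1 in the mixed form. Not every pair of equal replicate numbers exceeded 0.1 at 1 h, 144 h, 0 h against 24 h before or cycloheximide at 1 h. The correlations ran, in that order, from −0.025 to 0.651, −0.216 to 0.236, 0.043 to 0.306 and −0.015 to 0.33. There the block changed these adjusted p values: repressors of myogenesis 0.243 to 0.0186 at 1 h and 0.116 to 0.00437 with cycloheximide, DNA replication and mitosis 0.0487 to 0.0684 at 144 h, and over the day before induction myogenic factors 0.21 to 0.0298, adhesion 0.166 to 0.0298, matrix 0.0487 to 0.0822 and ribosome biogenesis 0.0525 to 0.0127. Of the named genes it added Id1 at 1 h (0.0218), Igf2 (0.0104) and Myc (0.046) at 144 h, and Cdkn1a (0.013), Fos (0.0436), Igf2 (6.51e-06) and Myh3 (0.000138) before induction, and no further named call there.

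Under the alternatives, values of named genes that were called as designed turned direction in 6 cases. Genes not called as designed and other probe sets of the same gene were not counted. With cycloheximide at 1 h Polr1b had −0.0405 after quantile normalization again, and Kirrel −0.0182 and Ptprc −0.0396 centred on housekeeping genes. Myof at 144 h had 0.11 without _s_at and _x_at probe sets, and at 24 h, with 0 h and 24 h before as the reference, Hspe1 had −0.0341 and Pik3ip1 0.0498. Leaving out an array ended 168 named gene calls and added 3. Other settings ended calls most often with only the groups compared (99 values), housekeeping centring (85), quantile normalization again (50), cyclic loess (43) and the mean of probe sets (37), and the block ended 0 and added 9.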

Other observations

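All comparisons and tests in this part were chosen only after the data were seen. The gene lists of cycloheximide were prompted by members already seen, so the test of each list used the members whose values had not been seen when it was written.

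Between 48 h and 96 h, genes of DNA replication and mitosis fell together. Their medians were 0.38 and 0.52 higher at 48 h than at 24 h, with at most 1 gene of either list called risen. Of 25 replication genes 23 fell and 0 rose (22 after quantile normalization again), and of 24 mitosis genes 20 fell and 0 rose (20). Top2a, the topoisomerase of chromosome separation, fell by 1.70 (SE 0.27), the cyclin Ccna2 by 1.50 (SE 0.25), the kinase Cdk1 by 1.41 (SE 0.23) and Pcna, the sliding clamp of replication, by 0.75 (SE 0.11), with n = 3 arrays at each time. Between 24 h and 48 h, 5 of 15 genes of cholesterol synthesis and uptake rose (4 after quantile normalization again), Insig1 by 1.24 (SE 0.23, adjusted p = 0.000507) and Cyp51 by 0.95 (SE 0.20). Of 14 genes of muscle energy metabolism 7 rose from 24 h to 48 h and 6 from 48 h to 96 h, and of 31 sarcomere genes 3 in each step. In all 708 genes changed from 24 h to 48 h (342 risen, 366 fallen), 844 from 48 h to 96 h (357 and 487) and 57 from 96 h to 144 h (38 and 19).

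Glucocorticoid receptor targets were higher with cycloheximide. At 3 h, 6 of the 8 members that had not been seen rose (4 after quantile normalization again), with a median of 0.64 against 0.19 over all genes (0.47 after normalization again), a percentile of 99.97 among 10000 random lists of like level. Mt2 rose by 2.38 (SE 0.14), Klf9 by 2.36 (SE 0.31) and Mt1 by 2.05 (SE 0.11). At 1 h 5 of the 8 rose (2 after normalization again). Of all 19 members 16 rose at 3 h (13 after normalization again), and 4 are also in another fixed list. Glucocorticoid signalling may take part in the response to the drug, but stress signals raise several of these genes too, and the test does not separate them.

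Host genes of small nucleolar RNAs, whose transcripts decay when translated, were higher with cycloheximide at 1 h. Of 8 members that had not been seen 5 rose (4 after quantile normalization again), with a median of 0.69 (0.50 after normalization again), a percentile of 100 among random lists of like level. Snhg12 rose by 2.12 (SE 0.20), and of the members seen before Snhg16 rose by 2.44 (SE 0.17) and Snhg17 by 2.35 (SE 0.16), while Snhg3 fell by 0.73 (SE 0.24). Of the 13 members listed 8 rose and 1 fell (6 and 2 after normalization again, when Dancr had also fallen). At 3 h 5 of the 8 rose and 1 fell, Snhg18 by 0.68 (SE 0.16), and of the members seen before Dancr fell by 1.65 (SE 0.26) and Snhg3 by 2.18 (SE 0.24). Snhg4, a host gene that was not on the list, was also among the largest called falls at 3 h. Slower decay of these transcripts when translation stops is a candidate explanation that stays untested here.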
